A study of Mus musculus with 30 samples.

How the data were processed

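RNA was extracted from sorted stem cells and made into libraries with a low-input kit, per the labels' protocols. The submitters' processing notes name FastQC, MultiQC, Salmon and DESeq2 and the mouse build GRCm38, without versions. The deposited table holds estimated counts of the kind Salmon gives, as whole numbers, for 17562 genes in 30 columns. The smallest sum of a gene over the columns was 11. The authors also deposited 11 tables of comparisons with a log2 fold change, a test score, its standard error, a p-value and an adjusted p-value per gene. In 89.7% of their rows the log2 fold change is not the score times its standard error, so those log2 values were shrunken by the authors, and they were not set beside fitted values as equals.

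Each column name equals the description of a sample. For 11 columns the title of the described sample holds another library code: the column's own code stands in the title of another sample for 10 and in no title for 1. Since the labels conflict, these 11 columns were not used for the main values, which rest on 19 libraries. The plan made before the data were examined had all samples in 1 fit with columns matched by title. The change to 19 libraries was made after the files had been seen and after the authors' deposited fold changes had been compared with simple log ratios under both matchings, before any model was fitted. It was kept after fits under all 3 matchings had been seen. Matching by title (29 columns) and by description (30 columns) are given as alternatives. The OHETX condition has no library among the 19, and its values come from the authors' deposited tables, whose direction (first-named condition over second) was read from their values.

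The estimated counts, already whole, were rounded and tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F-test, robust, TMM, filterByExpr by condition), in 1 fit over 6 conditions with a strain term, leaving 12 residual degrees of freedom and 15675 genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. A standard error is the log2 fold change divided by the root of its F. Group values are CPM with TMM factors, mean ± SD over libraries. The labels describe separate samples, and p-values measure the spread between them. The labels used do not say which joined mice were partners. Pairs were therefore not modelled, and libraries were treated as independent. Both partners of an isochronic pair may be among the libraries of OISO or of YISO, and p-values there may then be too small. The closest libraries of a group differed by a chi-square of 22.8 per degree of freedom, so no pair was a repeat within sampling noise. Symbols came from GENCODE by gene ID for 17547 of 17562 genes, with GRCm38 coordinates.

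Named genes followed a rule set before the data were examined: per main comparison the 12 largest rises and 12 largest falls among called genes with a mean log2 CPM of at least 1 and an established symbol, 5 and 5 in other comparisons, and the 3 smallest p per direction where under 3 passed. An established symbol is 1 that is not Gm with digits and does not end in Rik or -ps. Up to 4 members per list with the smallest adjusted p were named (up to 2 by mean log2 CPM where none passed), up to 6 per ageing set or overlap, and Ptprc, Cdkn2a, Cdkn1a and Slamf1 anywhere. In all, 25 gene lists were fixed in advance and tested with camera (limma 3.58.1; preset correlation 0.01, and an estimated one) and fry, adjusted over lists. The genes called in OCNT minus YCNT were followed with fry in OISO minus YISO, OHET minus OISO and YHET minus YISO, and by a score per library with 2-sided exact permutation tests, as planned before the data were examined. OHET minus YHET was added to these after the data were seen. The fry p-values of these sets were adjusted over the 8 set tests. fry tests whether genes of a set move on balance one way and does not compare the set with other genes.

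Alternatives were DESeq2 1.42.0, limma-voom with sample quality weights, RLE size factors, no filter, no strain term, only the conditions compared, 1 strain, a 2-fold minimum and leaving out each library. Leaving out all 3 OCNT libraries of B6, and title matching without OHETB6 replicate 4, were added after the data were seen. The fit was tested on simulated data with the real means, dispersions and library sizes and 200 changed genes. For OCNT minus YCNT it recovered 32 of 100 genes changed 2-fold and 78 of 100 changed 4-fold, with 3 false calls among 113. This simulation was run after the first fit of the real counts. Its changed genes were drawn from those whose mean CPM was at least 1 in log2. Otherwise all conditions and strains had the same mean and dispersion per gene. Libraries held 12269259 to 30932977 counts. Shares of counts in single libraries have 95% Wilson intervals, and a count of 0 was given a limit of 3 counts. Both cover counting error only.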

Results

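RNA sequencing measured gene expression in haematopoietic stem cells sorted from the bone marrow of male mice, in young animals of 8 to 12 weeks and old animals of 21 or 22 months. Some mice were left unjoined. Others were joined surgically so that 2 animals shared a circulation (parabiosis), either with a partner of like age (isochronic) or with a partner of the other age (heterochronic). Mice were of strain B6 or of BoyJ, its congenic partner that carries another form of the CD45 gene Ptprc. The labels give 30 samples in 11 groups, merged here over strain into 7 conditions: young and old unjoined controls (YCNT, 7 samples, and OCNT, 4), young and old isochronic (YISO, 4, and OISO, 6), young and old heterochronic (YHET, 3, and OHET, 4), and old cells recovered from the marrow of the young partner (OHETX, 2). For 10 columns of the count table the title and the description of the samples give different samples, and for 1 more the code is in no title, so the values below come from the 19 libraries on which both labels meet: 4 YCNT, 3 YISO, 2 YHET, 4 OCNT, 4 OISO and 2 OHET. None of the OHETX libraries is among them. These 19 libraries held 12269259 to 30932977 counts each, and 15675 genes entered the tests. The 95% Wilson intervals of shares and the limits given for counts of 0 cover counting error only.

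Old unjoined controls were set against young unjoined controls to compare ages without joining. Selp (ENSMUSG00000026580), the adhesion receptor P-selectin of platelets and endothelium on GRCm38 chromosome 1 at 164115264 to 164150026, was among the 12 genes that rose most. It stood at 254 ± 79.9 CPM (counts scaled to library size; SD, n = 4) in OCNT and 25.7 ± 7.56 in YCNT (n = 4), a log2 fold change of 3.31 (SE 0.35; adjusted p = 3.74e-05, edgeR quasi-likelihood test). Osmr (ENSMUSG00000022146), the oncostatin M receptor, rose by 4.02 (SE 0.63), from 2.34 ± 1.85 to 38.8 ± 6.15 CPM. Cldn5, a tight junction protein of endothelium, rose by 4.77 (SE 0.74), Tdrd9 by 4.36 (SE 0.60), Kcnb2, a potassium channel, by 4.41 (SE 0.71), Sbspon by 4.18 (SE 0.70) and Trpc1, a cation channel, by 3.61 (SE 0.63). The GABA receptor subunit Gabra4 reached 4.28 ± 1.86 CPM against 0.0336 ± 0.0426, and Spint1 5.51 ± 1.63 against 0.149 ± 0.237. Tmem215, Tmem117 and Ccn1 completed the 12 largest rises, and the OCNT and YCNT libraries overlapped for Ccn1.

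The 12 largest falls in the same comparison included the cytokine receptor Flt3, which marks progenitors with lymphoid potential, at 11.3 ± 1.48 CPM in OCNT and 41.3 ± 14.0 in YCNT (log2 fold change -1.64, SE 0.33; edgeR adjusted p = 0.0126). Rgs7bp changed by -3.25 (SE 0.51), Nlrp10 by -3.19 (SE 0.61), Mc5r by -2.59 (SE 0.60), Ipcef1 by -2.10 (SE 0.38) and Tent5a by -1.96 (SE 0.44). Ect2, which is needed for cytokinesis, changed by -1.71 (SE 0.28), and Ebi3, a cytokine subunit, by -1.70 (SE 0.41). Synpo2, Phldb2, Nlrc3 and Ankle1 were the others. In all, 179 genes rose and 42 fell. Slamf1, a surface marker of stem cells, rose by 1.29 (SE 0.24). Ptprc (log2 fold change -0.01, SE 0.09) and the cell cycle inhibitor Cdkn1a (0.84, SE 0.77) did not pass. Cdkn2a was not analysed here.

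Among the gene lists, 25 of 29 tested genes that earlier signatures place higher in old stem cells rose, and all 29 did when adjusted over the list alone. Cavin2 (log2 fold change 2.08, SE 0.19), Vwf, the von Willebrand factor of platelets (2.34, SE 0.26), and Alcam (1.39, SE 0.15) had the smallest adjusted p besides Selp. The list test gave an adjusted p of 6.75e-110 with a preset correlation (camera) and 4.98e-06 with an estimated correlation. Of 19 megakaryocyte and platelet genes, a list that also holds Selp, Vwf and Cavin2, 5 rose, and likewise 5 adjusted over the list alone (estimated correlation, adjusted p = 0.00372). Of 22 stem cell identity genes 3 rose, Slamf1, Pdzk1ip1 and Procr, and 8 adjusted over the list alone (estimated correlation, adjusted p = 0.0192). Of 11 genes placed lower in old stem cells, Flt3 and Arhgap15 fell, and 6 did adjusted over the list alone (estimated correlation, adjusted p = 0.0192). All 25 cell cycle genes had negative values. Aurkb, Mki67 and Cdk1 fell, 18 fell adjusted over the list alone, and the adjusted p of the list was 9.37e-20 with the preset and 0.0548 with an estimated correlation. These genes took 0.236% to 0.305% of counts in the 3 OCNT libraries of strain B6, 0.404% in OBJCNT replicate 1 (95% Wilson interval 0.402% to 0.406%) and 0.509% to 0.584% in YCNT. Among 20 immediate early and stress genes, which cell isolation also raises, Ier3, Junb and Klf6 rose, and 14 rose adjusted over the list alone. The adjusted p of that list was 0.139 with an estimated correlation. These genes took 0.431% to 0.477% of counts in the 3 OCNT libraries of strain B6 (95% Wilson intervals between 0.427% and 0.480%). In OBJCNT replicate 1, the OCNT library of BoyJ, they took 0.0593% (0.0584% to 0.0602%), and in any other library of the 19 at most 0.158% (0.156% to 0.160%). Without the 3 OCNT libraries of strain B6, a setting chosen after seeing the data, 21 genes were called in place of 221, with 1 OCNT library left that is assumed to vary like the other groups.

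**Figure D1:**
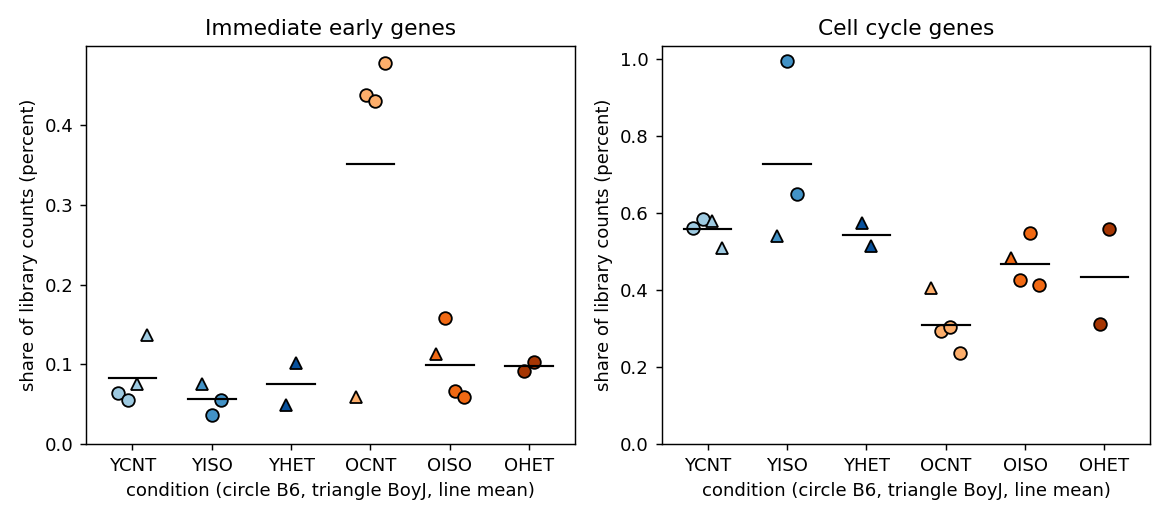
Share of each library's counts, in percent, taken by immediate early genes (left) and cell cycle genes (right), by condition. Points are the 19 libraries (circles B6, triangles BoyJ) and lines are means. The 3 B6 libraries of OCNT lie between 0.431% and 0.477% for immediate early genes, above all others.

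The count of 221 depended on single libraries and on the tool. It was 106 without YB6CNT replicate 1, 135 without YB6CNT replicate 3, 147 without OB6CNT replicate 2 and 123 without OB6CNT replicate 3. DESeq2 called 495 genes and limma-voom 738, while 339 were called with columns matched by title and 136 by description.

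Old isochronic mice were compared with young isochronic mice, which asks what age changed when both sides had undergone joining. Cldn5 again rose, to 15.6 ± 5.15 CPM (SD, n = 4) in OISO from 0.742 ± 0.616 in YISO (n = 3), a log2 fold change of 4.43 (SE 0.82; edgeR adjusted p = 0.0108). Osmr rose by 5.64 (SE 0.78), Kcnb2 by 4.16 (SE 0.81), Sbspon by 3.92 (SE 0.79) and C4b, a complement component with a close copy in the genome whose reads cannot be separated with certainty, by 4.57 (SE 0.80). The angiotensin receptor Agtr1a rose by 4.17 (SE 0.63), Eya4 by 5.21 (SE 0.81), Dlk1 by 5.31 (SE 1.06) and the filament protein gene Synm by 3.80 (SE 0.75). Gabra4 stood at 3.17 ± 1.78 CPM in OISO and at 0 in each YISO library, where a count of 0 (3 counts of the total as the limit) allows up to 0.108 to 0.15 CPM per library. Adgrg6 and Cntn1 completed the 12. In all, 107 genes rose and 9 fell. The 9 were Nlrp10 (-3.25, SE 0.63), Rgs7bp (-2.37, SE 0.50), Abcf2, Ebi3 (-2.00, SE 0.42), Cd37, Cdc45, BC055324, Pold3 and Arhgap30, and the OISO and YISO libraries overlapped for Abcf2. Cdc45 and Pold3 act in DNA replication. Slamf1 (0.68, SE 0.26, edgeR adjusted p = 0.296) and Cdkn1a (3.63, SE 0.90, edgeR adjusted p = 0.071) did not pass. The OISO and YISO libraries did not overlap for either gene.

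Of the 29 listed genes placed higher in old stem cells 22 rose, and 29 adjusted over the list alone (estimated correlation, adjusted p = 2.22e-05). Plscr2, a gene with close relatives, had a log2 fold change of 3.73 (SE 0.39), Alcam 1.68 (SE 0.17), Cavin2 1.81 (SE 0.21) and Gda, a guanine deaminase, 1.71 (SE 0.20). Of 19 megakaryocyte and platelet genes 4 rose, Cavin2, Selp, Vwf and Itgb3, and 8 adjusted over the list alone (estimated correlation, adjusted p = 0.003). All 25 cell cycle genes again had negative values. None of the 25 passed over all genes and 17 fell adjusted over the list alone, with an adjusted p of 4.38e-16 with the preset and 0.136 with an estimated correlation. The cell cycle genes took 0.995% of counts in YISOB6 replicate 1 (95% Wilson interval 0.991% to 0.999%), the highest share of the 19 libraries, and the count of 116 became 56 without it. It became 69 without OISOBJ replicate 1, 76 without OISOB6 replicate 3 and 76 without YISOB6 replicate 2. DESeq2 called 500 genes, and 233 were called with columns matched by title.

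The genes called by age in unjoined mice were followed in isochronic mice, whose libraries were on neither side of that comparison but entered the same fit. Of the 179 genes higher in OCNT, 176 had positive values in OISO against YISO (median log2 fold change 0.95; limma fry, adjusted p = 5.69e-07 over 8 set tests), and all 42 genes lower in OCNT had negative values (median -0.71; limma fry, adjusted p = 0.000265). Without YISOB6 replicate 1, which had the highest cell cycle share of the 19 libraries (0.995%), the medians were 0.89 and -0.41, for sets that can change with the setting. The 42 genes include Ect2, which is needed for cytokinesis, and how far cell cycle differences carry this set was not tested. The comparisons called 71 rising genes in common, where independent lists would share 1.22, and 4 falling genes, where independent lists would share 0.0241. The edgeR interaction called no gene for a difference between the comparisons in its age effect (0 of 15675, 736 at an unadjusted p under 0.05, 27 by DESeq2 and 1 by limma-voom), with 1 called without YISOBJ replicate 2 and 1 without OISOB6 replicate 3. If no gene differed, 784 of the 15675 would have an unadjusted p under 0.05 by chance. An ageing gene score per library, the mean log2 CPM of the 179 genes minus that of the 42, was 0.661 ± 0.317 in OISO (SD, n = 4) and -1.62 ± 0.382 in YISO (n = 3). A 2-sided exact permutation test of the score gave p = 0.0286, the smallest that 35 arrangements allow, and 0.114 adjusted over 4 such tests. Libraries of 1 isochronic condition may come from partners, which the labels used do not say and no test here took into account.

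**Figure D2:**
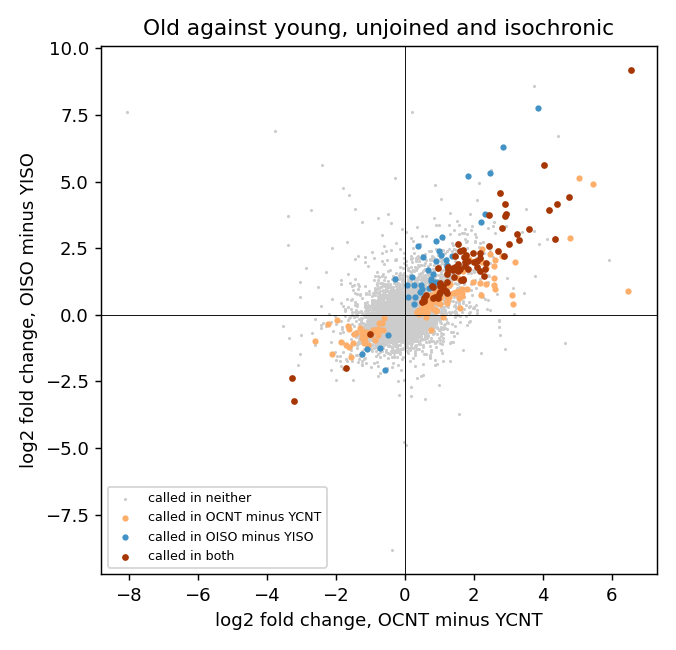
Log2 fold change of each gene with mean log2 CPM of at least 1 in OCNT minus YCNT (horizontal) and OISO minus YISO (vertical). Colours mark genes called in neither, either or both comparisons at an adjusted p under 0.05. Of all 179 genes that rose in OCNT, shown or below that level, 176 had a positive value in OISO minus YISO.

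Joining itself was addressed by isochronic against unjoined mice of the same age. In young mice, Ttc30a1 (log2 fold change 2.46, SE 0.48), Ide, the insulin-degrading enzyme (0.74, SE 0.16), and Cdc23 (0.60, SE 0.13) had the smallest p among positive values, and Ltbp4, Mipol1 and Npr2 among negative ones, each with an edgeR adjusted p of 0.379. No gene passed in YISO against YCNT with edgeR, while 1284 had an unadjusted p under 0.05 (784 by chance), DESeq2 called 94 and limma-voom 0. Without YISOBJ replicate 2, 2 genes were called. All 25 cell cycle genes had positive values (preset correlation, adjusted p = 4.16e-10), as did 58 of 63 histone genes (7.24e-13), 77 of 81 ribosomal protein genes (6.67e-15) and 67 of 76 nuclear oxidative phosphorylation genes (9.4e-11). Each of these lists had an adjusted p of 0.403 with an estimated correlation. YISOB6 replicate 1 stood apart, with 0.995% of its counts in cell cycle genes and 0.429% in histone genes (95% Wilson intervals 0.991% to 0.999% and 0.426% to 0.432%). The other YISO libraries had 0.541% to 0.648% and 0.233% to 0.240%, and the YCNT libraries 0.509% to 0.584% and 0.174% to 0.254%. In old mice, no gene passed in OISO against OCNT with edgeR, 802 had an unadjusted p under 0.05, near the 784 of chance, DESeq2 called 33 and limma-voom 42. The smallest p belonged to Nr4a1, an immediate early gene, with a log2 fold change of -3.67 (SE 0.64; edgeR adjusted p = 0.164), and to Tent5a, at 24.9 ± 8.75 CPM in OISO and 5.01 ± 2.45 in OCNT (n = 4 each; 2.32, SE 0.42; edgeR adjusted p = 0.164). Of 20 immediate early genes 19 had negative values and 14 fell adjusted over the list alone, against 0 over all genes (estimated correlation, adjusted p = 0.0769). The 3 OCNT libraries of strain B6 hold the high shares of these genes given above. Without OBJCNT replicate 1, 13 genes were called.

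Heterochronic joining had old and young mice share a circulation, and the cells of each were set against isochronic mice of the same age. In old mice Per1, a circadian clock gene, had 9.04 ± 2.94 CPM in OHET (n = 2) and 33.6 ± 7.02 in OISO (n = 4), a log2 fold change of -1.98 (SE 0.36; edgeR adjusted p = 0.122), and Sult6b1 and Slc25a27 followed among negative values. Mapk12, Zscan25 and Dab2ip led the positive values. All of these varied widely between the 2 OHET libraries, at 489 ± 674 CPM for Mapk12, 76.0 ± 93.1 for Zscan25, whose OHET and OISO libraries overlapped, and 113 ± 82.3 for Dab2ip. No gene passed with edgeR, 1732 had an unadjusted p under 0.05 (784 by chance), DESeq2 called 191 and limma-voom 0. The 179 genes higher in old controls had a median log2 fold change of 0.13 in OHET against OISO (127 positive; limma fry, adjusted p = 0.235), and the 42 lower genes -0.15 (29 negative; limma fry, adjusted p = 0.275). The ageing gene score was 0.911 ± 0.63 in OHET (n = 2), against 0.661 ± 0.317 in OISO (n = 4; 2-sided exact permutation p = 0.533, smallest possible 0.0667). Ribosomal protein genes had positive values in 74 of 81 (preset correlation, adjusted p = 1.45e-09), with an adjusted p of 0.81 with an estimated correlation. They took 9.84% of counts in OHETB6 replicate 3 (95% Wilson interval 9.83% to 9.86%), 8.83% in OHETB6 replicate 4 (8.82% to 8.84%) and 8.72% to 8.97% in OISO. Without OHETB6 replicate 3 the remaining OHET library, OHETB6 replicate 4, gave a median of -0.04 for the genes higher in old controls and 0.24 for the lower ones. Without OHETB6 replicate 4 the medians were 0.30 and -0.43. These sets can change with the setting.

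In young mice Chst2, a sulfotransferase, had 26.2 ± 4.62 CPM in YHET (n = 2) and 5.53 ± 1.88 in YISO (n = 3), a log2 fold change of 2.44 (SE 0.47; edgeR adjusted p = 0.594). Clgn and Slc7a7 followed among positive values, and Sec16b, Gucy1a1 and E330009J07Rik among negative ones. No gene passed with edgeR, 1050 had an unadjusted p under 0.05 (784 by chance), DESeq2 called 55 and limma-voom 0. It was 1 gene without YHETBJ replicate 1 and 1 without YHETBJ replicate 3. The 42 genes lower in old controls had negative values in 38 (median log2 fold change -0.37; limma fry, adjusted p = 0.085), and the 179 higher genes were positive in 123 (median 0.15; limma fry, adjusted p = 0.164). By unadjusted fry the genes lower in old controls, a set that can change with the setting, passed without YISOBJ replicate 2 (median -0.59), YBJCNT replicate 3 (-0.24), OB6CNT replicate 2 (-0.34), OB6CNT replicate 3 (-0.35) or YISOB6 replicate 2 (-0.41). The control libraries can act through the choice of genes and through the shared strain term and dispersions, which were not separated. The score was -0.919 ± 0.0444 in YHET (n = 2) and -1.62 ± 0.382 in YISO (n = 3; 2-sided exact permutation p = 0.2, smallest possible 0.1). Histone genes were negative in 59 of 63 and cell cycle genes in all 25, and each list had an adjusted p of 0.603 with an estimated correlation. YISOB6 replicate 1, with 0.995% of its counts in cell cycle genes and 0.429% in histone genes, stood apart from the other YISO libraries (0.541% to 0.648% and 0.233% to 0.240%), and the YHET libraries had 0.514% to 0.573% and 0.212% to 0.232%. YISOB6 replicate 1 also had the lowest ageing gene score of YISO, -2.04. Of 13 neutrophil and monocyte genes, markers of other cell types, 11 had positive values, none passed over all genes and 3 were higher adjusted over the list alone. That list had an adjusted p of 0.00176 with the preset and 0.603 with an estimated correlation. These genes took 0.0449% of counts in YHETBJ replicate 1 (95% Wilson interval 0.0441% to 0.0457%), 0.0215% in YHETBJ replicate 3 (0.0207% to 0.0223%) and 0.0195% to 0.0287% in YISO. The difference between the old and the young heterochronic effect was called for 0 genes by edgeR, with 1345 at an unadjusted p under 0.05 (784 by chance), 83 calls by DESeq2 and 0 by limma-voom. It was 55 without OHETB6 replicate 3 and 1 without YHETBJ replicate 1. In simulated data with these libraries, 16 of 100 genes changed 2-fold and 65 of 100 changed 4-fold were recovered for OHET minus OISO, and 12 and 59 for YHET minus YISO. The simulated dispersion was shared by all conditions, while the OHET libraries were the most unlike pair within a group (chi-square of 122.5 per degree of freedom). The recovery given for OHET may therefore be too high.

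Between heterochronic mice of different age, 18 genes were higher in OHET and 6 lower. Clca3a1 (ENSMUSG00000056025), a chloride channel regulator with close copies, stood at 456 ± 18.5 CPM in OHET and 68.4 ± 7.65 in YHET (n = 2 each; log2 fold change 3.02, SE 0.38; edgeR adjusted p = 0.00226). Osmr rose by 5.57 (SE 1.06), Gpr183 by 3.45 (SE 0.65) and the lipase Lpl by 3.41 (SE 0.59), and Gabra4 was at 10.3 ± 0.966 CPM against 0 in both YHET libraries, where a count of 0 allows up to 0.115 and 0.219 CPM. Zfp14 (-4.71, SE 0.76), Tcam1, Tmem253, Anxa6 and Gbp10 were lower. Of the 29 listed genes placed higher in old stem cells 5 rose, and 25 adjusted over the list alone (estimated correlation, adjusted p = 0.00117). Of 19 megakaryocyte and platelet genes 2 rose, and 9 adjusted over the list alone (estimated correlation, adjusted p = 0.00355). In a test added after the data were seen, 172 of the 179 genes higher in old controls had positive values (median 0.97; limma fry, adjusted p = 3.46e-05) and 37 of the 42 lower genes negative ones (median -0.49; limma fry, adjusted p = 0.0312). With an estimated correlation these sets had an adjusted p of 0.000224 and 0.0806, so the call of the lower genes was lost (limma camera). Every OHET library was B6 and every YHET library BoyJ, so this contrast rests on the strain term of the other conditions. Mice that shared a circulation may stand on both sides, which the labels used do not say and the fit ignored. The count was 0 without YHETBJ replicate 1, 12 without YHETBJ replicate 3 and 274 without OHETB6 replicate 3. Without the strain term 42 genes were called, 18 of them among the 24, and with only the conditions compared 1. DESeq2 called 326 and limma-voom 1, and 0 were called with columns matched by description, labels that are argued against under Other observations.

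**Figure D3:**
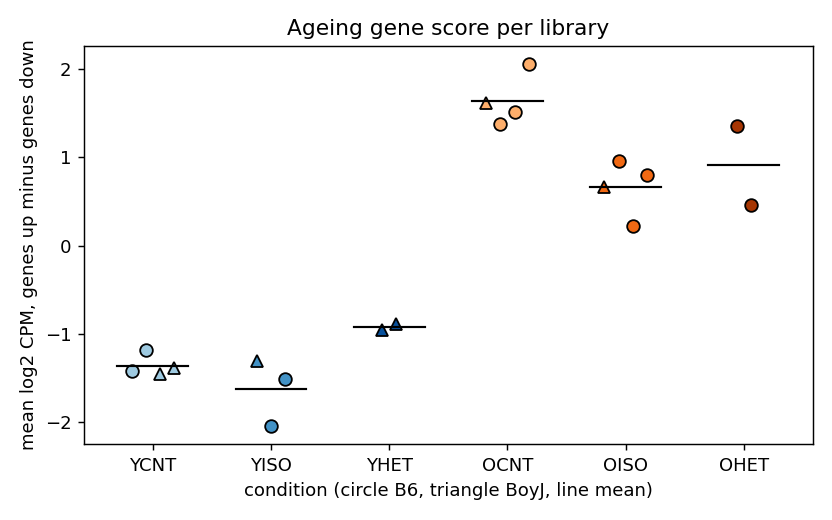
Ageing gene score of each of the 19 libraries: the mean log2 CPM of the 179 genes higher in OCNT minus that of the 42 genes lower. Circles are B6, triangles BoyJ and lines means. The genes were chosen by OCNT against YCNT, so those conditions are not compared. OISO averages 0.661 and YISO -1.62.

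Against unjoined mice of the same age, YHET minus YCNT and OHET minus OCNT each called no gene with edgeR, with 805 and 1793 genes at an unadjusted p under 0.05. Chance alone would give 784 in each, so the 805 of YHET minus YCNT lies near that level. DESeq2 called 38 and 203, and limma-voom 0 and 5. For YHET minus YCNT 1 gene was called without YHETBJ replicate 3. For OHET minus OCNT it was 709 without OHETB6 replicate 3, 12 without OBJCNT replicate 1 and 2 without OHETB6 replicate 4. Gstm1, a glutathione transferase, had the smallest p among positive values in the first, at 187 ± 11.1 CPM in YHET (n = 2) and 99.8 ± 16.5 in YCNT (n = 4; edgeR adjusted p = 0.845). Gins2, a DNA replication factor, had it in the second, at 181 ± 18.6 CPM in OHET (n = 2) and 85.7 ± 18.6 in OCNT (n = 4; edgeR adjusted p = 0.0748), beside Per1 among negative values. Of 63 histone genes 29 were higher in OHET than OCNT adjusted over the list alone, against 0 over all genes, and the list had an adjusted p of 0.351 with an estimated correlation. Histone genes took 0.0834% to 0.117% of counts in the 3 OCNT libraries of strain B6, 0.201% in OBJCNT replicate 1 (95% Wilson interval 0.199% to 0.202%), 0.172% in OHETB6 replicate 3 (0.170% to 0.174%) and 0.312% in OHETB6 replicate 4 (0.310% to 0.314%). Of 13 neutrophil and monocyte genes 12 had positive values in OHET against OCNT, none passed over all genes or adjusted over the list alone, and the list had an adjusted p of 0.00677 with the preset and 0.403 with an estimated correlation. They took 0.0736% of counts in OHETB6 replicate 4 (95% Wilson interval 0.0726% to 0.0747%), 0.0231% in OHETB6 replicate 3 (0.0225% to 0.0237%) and 0.0198% to 0.0255% in OCNT.

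For old cells recovered from the young partner, the values are those of the authors' deposited tables. Across 9753 genes these had a Pearson r of 0.791 to 0.827 with title-matched edgeR fits and -0.0661 to 0.265 with description-matched ones. They thus follow the titles, and their values too hold only if the titles name the right samples. The authors' deposited table of OHET and OHETX calls 518 genes, 205 of them higher in OHETX. The log2 fold changes there are shrunken by the authors. In the authors' deposited table Rnmt, an mRNA cap methyltransferase, has a log2 fold change of -2.46 for OHET over OHETX, and Rgs2 (-1.84), Vegfa, a vascular growth factor (-1.74), Camta1 (-1.77) and Ikbke (-1.68) are also higher in OHETX. Gnaz (2.05), Zfr2 (1.88), Card10 (1.86), Fam169a (1.86) and Tacr1 (1.76) are lower in OHETX in the authors' deposited table. Of the 179 genes higher in old controls, 134 are lower in OHETX than OHET in the authors' deposited table, and 10 of the 11 called are lower, Vwf and Cavin2 among them. Immediate early genes are also higher in OHETX in the authors' deposited table, 19 of 20 of them (median log2 fold change -0.70 for OHET over OHETX), as are 12 of 14 neutrophil and monocyte genes (median -0.43). By title, the OHETX libraries differ in this: OHETB6X replicate 1, with 7659468 counts and an ageing gene score of -0.293, held 0.419% of its counts in immediate early genes (95% Wilson interval 0.414% to 0.424%), and OHETB6X replicate 2, with 16416562 counts and a score of 0.254, held 0.103% (0.101% to 0.104%). Ctse, a gene higher in BoyJ, was at a log2 CPM of 7.43 in OHETB6X replicate 1 and 5.22 in OHETB6X replicate 2, by title. Of the B6 libraries of the 19, OHETB6 replicate 4 had the highest level, 7.31, and OISOB6 replicate 5 the next, 6.85. Cells of the BoyJ partner stay open for OHETB6 replicate 4 too, so its level is no clean B6 limit. Whether cells of the young BoyJ partner in the sort lowered the ageing genes in OHETX was not tested. The authors' deposited table of OISO and OHETX calls 423 genes, with 143 of the 179 lower in OHETX, and 19 of 20 immediate early and 13 of 14 neutrophil and monocyte genes higher. The authors' deposited table of YHET and OHETX calls 226, with 137 of the 179 higher in OHETX, Selp, Clu and Plscr2 among the 15 called, and all 20 immediate early and 13 of 14 neutrophil and monocyte genes higher. With columns matched by title, edgeR called 35, 30 and 4 genes in these comparisons, and with columns matched by description 0 in each. The counts by description rest on labels that are argued against under Other observations.

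Between the strains, BoyJ minus B6 over all conditions, Ctse and Cxcr4 were higher in BoyJ. Ctse (ENSMUSG00000004552), the protease cathepsin E on GRCm38 chromosome 1 at 131638306 to 131675505, had a log2 fold change of 3.84 (SE 0.29; edgeR adjusted p = 5.61e-06). Cxcr4, the receptor that retains stem cells in the marrow (chromosome 1, 128588199 to 128592293), had 1.65 (SE 0.17; edgeR adjusted p = 7.25e-05). Ptprc itself had 0.05 (SE 0.07). DESeq2 called 20 genes, limma-voom 2, and 0 were called with columns matched by description. Ctse lay on the side of the described strain in only 6 of the 11 columns with conflicting labels. The 0 by description therefore cannot test how stable the strain calls are.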

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

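The tests of the immediate early genes in this part were chosen after the result was seen, while the search for samples far from the rest of their group was planned. It covered 25 sets of values, each of 1 measure in 1 condition with at least 4 libraries, and named 6 libraries, where chance alone names about 1 in 20 groups.

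In the unjoined old mice, OBJCNT replicate 1, the BoyJ library, held 0.0593% of its counts in immediate early genes (95% Wilson interval 0.0584% to 0.0602%), far below the 0.431% to 0.477% of the 3 B6 libraries of OCNT. Age alone is argued against as the whole cause of the high shares, since the 7 other old libraries of the 19 reached at most 0.158%. High shares were not confined to unjoined mice by either label of 1 column. This column, OHETB6X replicate 1 by title and YHETBJ by description, held 0.419% (0.414% to 0.424%) at 7659468 counts. Both labels name joined mice, and by description the cells would be young. OISOB6 replicate 1 by title held 0.182% (0.181% to 0.184%). Isolation or handling of the 3 libraries may have raised these genes, which respond within minutes to hours to stress. The lowest share of the 3, 0.431%, lies above the 0.136% of the highest young library of the 19. Handling as a cause stays open because the labels give no day of preparation. A strain difference limited to unjoined old mice stays open as untested, with 1 BoyJ library there. The 5 B6 libraries of OISO and OHET, at 0.0591% to 0.158%, speak against a strain difference in old mice at large.

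YB6CNT replicate 3 had a total count of 30.933 in units of 1e+06, while the other YCNT libraries had 20.9 to 21.8. YB6CNT replicate 1 held 0.0399% of its counts in neutrophil and monocyte genes (0.0390% to 0.0407%), and the others of YCNT 0.0197% to 0.0219%. OISOB6 replicate 5 held 0.0852% in the same genes (0.0841% to 0.0864%), and the others of OISO 0.0207% to 0.0248%. OISOBJ replicate 1 held 8.97% in ribosomal protein genes (8.96% to 8.99%), and the others of OISO 8.72% to 8.76%. OISOB6 replicate 4 held 5.38% in mitochondrially encoded genes (5.37% to 5.40%), and the others of OISO 4.70% to 4.76%.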

How the results depend on the processing

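Leaving out all 3 B6 libraries of OCNT, and title matching without OHETB6 replicate 4, were tests chosen after the data were seen, and the others were planned. The cause was not tested for any change below, except that fewer samples or a stricter fold enter some alternatives by construction. For OCNT minus YCNT the 221 calls became 495 with DESeq2 (220 shared), 738 with limma-voom (220), 359 with only the conditions compared (202), 339 with columns matched by title (195), 136 by description (104), 86 in B6 alone (53), 145 at a 2-fold minimum (145) and 21 without all 3 B6 libraries of OCNT (18). For OISO minus YISO the 116 calls became 500 with DESeq2 (116 shared) and 233 with columns matched by title (102). For OHET minus YHET the 24 calls became 326 with DESeq2 (24 shared), 42 without the strain term (18), 1 with only the conditions compared, 1 with limma-voom and 0 by description.

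Where edgeR called 0 genes, DESeq2 called 94 in YISO minus YCNT, 33 in OISO minus OCNT, 55 in YHET minus YISO, 191 in OHET minus OISO, 38 in YHET minus YCNT and 203 in OHET minus OCNT. It called 27 in the interaction of age with isochronic joining and 83 in that of age with heterochronic joining. In the same order, edgeR had 1284, 802, 1050, 1732, 805, 1793, 736 and 1345 genes at an unadjusted p under 0.05. By chance alone 784 would be found in each, so 802 and 805 lie near that level and 736 below it. With limma-voom OISO minus OCNT had 42 calls, OHET minus OCNT 5, the age with isochronic joining interaction 1 and the rest of these 0. B6 alone gave 6 in OISO minus OCNT and 6 in OHET minus OCNT, and leaving out all 3 B6 libraries of OCNT 1 and 1. OHET minus OCNT also had 5 with only the conditions compared, 4 by title and 2 by description. The 2 strain calls became 20 with DESeq2 and 0 by description. All counts by description in this part rest on labels that are argued against under Other observations, so they cannot test stability. The authors' deposited table counts for OHETX of 518 (OHET), 423 (OISO) and 226 (YHET) became 35, 30 and 4 with edgeR by title (33, 26 and 3 shared) and 0, 0 and 0 by description. DESeq2, RLE size factors, no filter, no strain term, limma-voom, a 2-fold minimum, only the conditions compared and leaving out single libraries were not run for OHETX.

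Leaving out each library in turn gave 106 to 186 calls in OCNT minus YCNT, 56 to 164 in OISO minus YISO, 0 to 2 in YISO minus YCNT, 0 to 13 in OISO minus OCNT, 0 to 1 in YHET minus YISO, 0 to 530 in OHET minus OISO, 0 to 1 in YHET minus YCNT, 0 to 709 in OHET minus OCNT and 0 to 274 in OHET minus YHET. It gave 0 to 1 and 0 to 55 for the interactions and 2 to 3 for the strains. OHET and YHET keep 1 library in such a setting, which is assumed to vary like the other groups. Medians of the genes higher in old controls ranged from 0.89 to 1.39 in OISO minus YISO, -0.0424 to 0.30 in OHET minus OISO and 0.03 to 0.25 in YHET minus YISO, and those of the lower genes from -0.90 to -0.41, -0.43 to 0.24 and -0.59 to -0.16. The calls in old controls change with the setting, so these sets can hold other genes than the 179 and 42. In YHET minus YISO the set of higher genes came past the unadjusted fry threshold without the strain term (median 0.18), and the set of lower genes with no filter (-0.39), without the strain term (-0.36) and with the 200 genes of smallest p as the source (-0.37). Among named genes, 1547 values kept direction and side, 271 lost the threshold, 87 gained it and 1 reversed, Gbp10 in OHET minus YHET with columns matched by description (0.22). In simulated data with the real library sizes, group sizes and dispersions, 32 of 100 genes changed 2-fold were recovered in OCNT minus YCNT, and depth was not varied, so its part was not tested.

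The list tests moved most with the set test. Adjusted p-values of lists past the threshold with the preset correlation of camera (limma) and not with an estimated correlation follow, by comparison. OCNT minus YCNT had lymphoid and cell cycle 0.0548, neutrophil 0.509, erythroid, inflammatory and histones 0.17, immediate early and quiescence 0.139, chromatin 0.122, ribosomal 0.155. OISO minus YISO had HSC ageing down, cell cycle and p53 0.136, HSC identity 0.183, inflammatory 0.291, immediate early 0.604, oxidative phosphorylation 0.35, histones 0.406. YISO minus YCNT had immediate early and mitochondrial 0.79, cell cycle, ribosomal, oxidative phosphorylation and histones 0.403. OISO minus OCNT had HSC ageing up and plasma cell 0.17, HSC ageing down 0.28, HSC identity, immediate early, chromatin and histones 0.0769, neutrophil 0.391, erythroid 0.281, cell cycle 0.0821, ribosomal 0.758. YHET minus YISO had HSC ageing up, neutrophil, cell cycle, unfolded protein, oxidative phosphorylation and histones 0.603, immediate early and ribosomal 0.715. OHET minus OISO had interferon response, ribosomal and oxidative phosphorylation 0.81. YHET minus YCNT had ribosomal 0.992. OHET minus OCNT had myeloid progenitor, immediate early, cell cycle and histones 0.351, neutrophil and oxidative phosphorylation 0.403, ribosomal 0.479. OHET minus YHET had HSC identity 0.384, myeloid progenitor and quiescence 0.409, ribosomal 0.431, histones 0.808. The interaction (OISO minus YISO) minus (OCNT minus YCNT) had neutrophil, immediate early, ribosomal and oxidative phosphorylation 0.611, mitochondrial 0.659. The interaction (OHET minus OISO) minus (YHET minus YISO) had cell cycle, unfolded protein, ribosomal, oxidative phosphorylation, mitochondrial and histones 0.742. BoyJ minus B6 had HSC ageing up, erythroid, ribosomal, oxidative phosphorylation, mitochondrial and histones 0.425, megakaryocyte and homing 0.197.

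With fry (limma) in place of camera the adjusted p-values of lists no longer past the threshold were these. For OCNT minus YCNT fry gave neutrophil 0.375, erythroid 0.0769, inflammatory and histones 0.0655, immediate early 0.0637. For OISO minus YISO fry gave inflammatory 0.0857, immediate early 0.369, cell cycle 0.0513, oxidative phosphorylation 0.168, histones 0.282. For YISO minus YCNT fry gave immediate early and mitochondrial 0.658, cell cycle, ribosomal, oxidative phosphorylation and histones 0.241. For OISO minus OCNT fry gave HSC ageing up 0.239, HSC ageing down 0.346, HSC identity 0.108, plasma cell 0.219, neutrophil 0.441, erythroid 0.36, immediate early and cell cycle 0.14, ribosomal 0.729, histones 0.111. For YHET minus YISO fry gave HSC ageing up, neutrophil and oxidative phosphorylation 0.56, immediate early 0.685, cell cycle 0.559, unfolded protein and histones 0.506, ribosomal 0.679. In OHET minus OISO the values were interferon response, ribosomal and oxidative phosphorylation 0.466. In YHET minus YCNT the values were ribosomal 0.973. In OHET minus OCNT the values were myeloid progenitor and immediate early 0.219, neutrophil and ribosomal 0.28, cell cycle 0.205, oxidative phosphorylation 0.229, histones 0.142. In OHET minus YHET the values were HSC identity 0.0932, myeloid progenitor 0.188, quiescence and ribosomal 0.159, histones 0.601. In (OISO minus YISO) minus (OCNT minus YCNT) the values were neutrophil, ribosomal and oxidative phosphorylation 0.638, immediate early and mitochondrial 0.67. In (OHET minus OISO) minus (YHET minus YISO) the values were cell cycle and mitochondrial 0.621, unfolded protein, ribosomal, oxidative phosphorylation and histones 0.552. In BoyJ minus B6 the values were HSC ageing up 0.404, megakaryocyte 0.154, erythroid and histones 0.351, homing 0.148, ribosomal 0.182, oxidative phosphorylation and mitochondrial 0.378. The chromatin list of OISO minus YISO came past it with fry (adjusted p = 0.0418).

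Without the strain term, adjusted p-values of lists that were no longer past the threshold (limma) were, by comparison, mitochondrial 0.101 in YISO minus YCNT, and immediate early 0.0909, ribosomal 0.99 in YHET minus YISO, and histones 0.643 in OHET minus YHET, and mitochondrial 0.0737 in (OISO minus YISO) minus (OCNT minus YCNT), and unfolded protein 0.117, mitochondrial 0.206 in (OHET minus OISO) minus (YHET minus YISO). Those that came past it were neutrophil 0.0468 in OISO minus YISO, and HSC ageing up 0.0479, oxidative phosphorylation 0.00702 in YHET minus YCNT. Of these list results 717 kept their direction and their side of the threshold under an alternative, 154 lost the threshold and 4 gained it. The cause was not tested.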

Other observations

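The tests of the library OHETB6 replicate 4, of the sample codes and of the genes near Ptprc were chosen after the results were seen, while the splits of the libraries and the ageing sets and scores of OHETX were planned.

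Single members of other gene groups rose in old against young unjoined mice, while several of these groups had mostly negative values. Of 13 myeloid progenitor genes Prtn3, a protease of granule-forming cells, rose (log2 fold change 1.68, SE 0.17; edgeR adjusted p = 3.74e-05), and 1 of 9 T and NK cell genes, Klrb1c, rose (2.81, SE 0.48; edgeR adjusted p = 0.00334). Kdr, a receptor for vascular growth factor, was the 1 of 9 endothelial and stromal genes that rose (2.62, SE 0.44), Socs3, an inhibitor of cytokine signals, the 1 of 18 inflammatory genes (3.19, SE 0.76), Txnip the 1 of 12 quiescence genes (0.75, SE 0.18) and the integrin Itga6 the 1 of 17 homing genes (0.97, SE 0.13). Positive values were found in 4 of 13 myeloid progenitor genes (estimated correlation, adjusted p = 0.873), 2 of 9 T and NK cell genes (adjusted p = 0.89), 1 of 13 neutrophil and monocyte genes (adjusted p = 0.509) and 7 of 17 homing genes (adjusted p = 0.851, all by limma camera). YB6CNT replicate 1 held 0.0399% of its counts in neutrophil and monocyte genes, the other YCNT libraries 0.0197% to 0.0219% and OCNT 0.0198% to 0.0255%. Of 15 erythroid genes 2 had positive values, none passed over all genes and 4 fell adjusted over the list alone. The erythroid list had an adjusted p of 0.00111 with the preset and 0.17 with an estimated correlation (limma camera). Erythroid genes took 0.128% of counts in YB6CNT replicate 1, 0.0846% to 0.0967% in the other YCNT libraries and 0.0758% to 0.100% in OCNT. Of 81 ribosomal protein genes 5 rose and 36 did adjusted over the list alone, while the list had an adjusted p of 0.155 with an estimated correlation. OBJCNT replicate 1 held 10.5% of its counts in these genes (95% Wilson interval 10.47% to 10.50%), the other OCNT libraries 8.23% to 8.85% and YCNT 7.60% to 8.78%. None of 24 interferon response genes passed, and 1 rose and 1 fell adjusted over the list alone (estimated correlation, adjusted p = 0.89). All 14 genes of the p53 and senescence list had positive values and none passed (estimated correlation, adjusted p = 0.17).

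Between joined and unjoined old mice no gene of these groups passed over all genes. Histone genes, whose copies are near-identical, had positive values in 55 of 63, with 22 higher in OISO adjusted over the list alone (estimated correlation, adjusted p = 0.0769). Of 25 cell cycle genes 24 had positive values, with 6 higher adjusted over the list alone (estimated correlation, adjusted p = 0.0821). The low side of both lists is that of the 3 OCNT libraries of strain B6 with the high immediate early shares, which held 0.0834% to 0.117% of counts in histone genes and 0.236% to 0.305% in cell cycle genes. OBJCNT replicate 1 held 0.201% (95% Wilson interval 0.199% to 0.202%) and 0.404% (0.402% to 0.406%), and the OISO libraries 0.165% to 0.251% and 0.412% to 0.548%. Of 13 neutrophil and monocyte genes 10 had positive values, with 1 higher adjusted over the list alone and an adjusted p of 0.00113 with the preset and 0.391 with an estimated correlation (limma camera). OISOB6 replicate 5 held 0.0852% of its counts in them (95% Wilson interval 0.0841% to 0.0864%), the other OISO libraries 0.0207% to 0.0248% and OCNT 0.0198% to 0.0255%. Of 15 erythroid genes 10 had positive values, with 2 higher adjusted over the list alone and an adjusted p of 0.00492 with the preset and 0.281 with an estimated correlation (limma camera). OISOB6 replicate 5 stood apart here too, with 0.116% of its counts in erythroid genes. The other OISO libraries had 0.0712% to 0.0789% and OCNT 0.0758% to 0.100%. The reverse view of the age comparison gave like directions: of the 107 genes that rose in OISO against YISO, 106 had positive values in OCNT against YCNT, and all 9 that fell had negative ones.

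Splits of the libraries of a pair of conditions, fitted alone, tested how often a random division called as many genes as the real one. For OCNT minus YCNT the real split called 359 genes and the highest other split 1, so 1 of 35 splits gave as many. For OISO minus YISO it was 84 genes against 1, again in 1 of 35 splits. Both argue against chance but do not exclude it. The share of 1 of 35 is the lowest possible here and was not adjusted over the comparisons tested. Splits that mix the ages also carry the age difference in their spread, which lowers their calls. For YISO minus YCNT and OISO minus OCNT the splits say nothing about chance: the real splits called 0 genes with edgeR, so that 35 of 35 splits give at least as many whatever the data, and the highest others called 2 and 4. At an unadjusted p under 0.05 the fit of all 19 libraries had 1284 and 802 genes in these comparisons (784 by chance in each), DESeq2 called 94 and 33, and limma-voom 0 and 42.

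With columns matched by title, the 256 genes then higher in old controls had a median log2 fold change of -0.33 in OHETX against OHET (193 lower; limma fry, adjusted p = 0.039) and -0.25 against OISO (183 lower; limma fry, adjusted p = 0.039), and an adjusted p of 0.178 in both with an estimated correlation. The 83 lower genes had medians of 0.11 and 0.20 (limma fry, adjusted p = 0.278 and 0.201). The score was -0.0194 ± 0.387 in OHETX (n = 2) and 0.743 ± 0.277 in OISO (n = 6; 2-sided exact permutation p = 0.0714, smallest possible 0.0357). It was 0.782 ± 0.724 in OHET (n = 4; 2-sided exact permutation p = 0.2 against OHETX, smallest possible 0.0667). Of the OHETX libraries by title, OHETB6X replicate 1 had a score of -0.293, 7659468 counts in all and 0.419% of them in immediate early genes (95% Wilson interval 0.414% to 0.424%). OHETB6X replicate 2 had a score of 0.254, within the OISO range of 0.222 to 0.960, 16416562 counts and 0.103% (0.101% to 0.104%). The values of this paragraph hold only if the titles name the right samples.

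OHETB6 replicate 4 stood apart from the other libraries. In it 168 genes lay more than 5 SD below the mean of the others and 50 above, against at most 22 and 10 in any other library. It held 0.0736% of its counts in neutrophil and monocyte genes (95% Wilson interval 0.0726% to 0.0747%) and 0.557% in cell cycle genes (0.554% to 0.560%), against 0.0231% (0.0225% to 0.0237%) and 0.311% (0.309% to 0.314%) in OHETB6 replicate 3. Whether cells of another type set it apart was not tested, and OISOB6 replicate 5 held 0.0852% in neutrophil and monocyte genes. Low depth is argued against, since its total count, 27.1 in units of 1e+06, lies above the median of the others, 22.5. Lower library complexity stays open: 15025 genes were detected in it against at least 15169 in every other library. It also had 97 genes under 1 CPM where the median of the others was at least 5 CPM, against at most 47 in any other library. Genes that were low in this library for any reason move both counts, so they cannot decide the question. The 50 highest genes held 14.3% of its counts, within the 13.0% to 16.3% of the other libraries. Cells of the BoyJ partner in the sort stay open: its ageing gene score of 0.466 lies within the OISO range of 0.222 to 0.960, but the 16.1% of BoyJ RNA that its Ctse level would need shifts the score by 0.254, less than the SD of 0.317 over OISO, so the bound set for this test could not decide it.

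For the 11 columns with conflicting labels, 10 named differently by title and description and 1 in no title, Ctse and the ageing gene score were set against the strain and age of each label, with sides parted midway between the libraries whose labels meet (8.22 for log2 CPM of Ctse and -0.332 for the score). The descriptions are argued against, since both measures lie on the described side in 4 of 11 columns, and 5 columns lie on the other side beyond the limits of those libraries. In each of the 10 columns, the title with the column's code was that of the sample described for the next column, a shift along the column order. The titles remain a candidate explanation, with both measures on the titled side in 10 of 10 columns, but 4 of the 10 fall between the limits in the score, and 1 of these in Ctse too, so that 6 lie beyond the limits for both. Across 9753 genes, which are not independent replicates, the authors' deposited fold changes had a Pearson r of 0.775 to 0.847 with the title-matched fits of the 11 tables and of -0.0661 to 0.752 with the description-matched fits.

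Genes near Ptprc differed between the strains more often than genes elsewhere. Within 20 Mb of Ptprc, 12 of 188 genes (6.38%) had an unadjusted p under 0.01 in BoyJ minus B6, against 200 of 15452 elsewhere (1.29%; odds ratio 5.2, Fisher's exact test p = 9.92e-06), with 7 higher and 5 lower in BoyJ. The stretch of chromosome 1 from 130 to 140 Mb ranked 1 of 226 windows, with 10 of 85 genes (11.8%). Neighbouring genes are not independent, and no cause was tested.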
